A study of Homo sapiens with 4 samples.

How the data were processed

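The series consists of 4 human ChIP-seq libraries from SH-SY5Y cells treated with 10 uM retinoic acid for 8 days. Groups were taken from the sample titles: a CHD5 pull-down, a control pull-down, an H3K27me3 precipitation and input DNA, with 1 library each. Per the labels' protocols, cells were cross-linked with formaldehyde, chromatin was sheared by sonication, the tagged protein was captured on streptavidin beads, and libraries were sequenced on an Illumina instrument. Since the libraries stand alone, no replicate comparison, leave-one-out run or pairing was possible, and no p-value is given for a difference between groups.

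A region list for CHD5 and one for H3K27me3 were used, and region lists for the control pull-down and input were not used here. Both lists are MACS peak calls, per the file headers, which name 1 library each, so peaks are taken as called per library. The genome build is hg19, per the submitters' processing notes. The MACS version, its threshold, the background library it was given and the aligner are not given in the sources used here. The choice of background library matters, because a pull-down called without a matched control also lists places that shear or capture well. It also matters that MACS builds narrow peaks: a broad mark such as H3K27me3 can then be split into many short regions, which is why joined domains were examined as well.

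Each region carries a score made by the authors' peak caller, deposited with the list. The smallest deposited score is 50 in both lists and the scale is not stated, so the score was used only within its own list. It served to rank and filter regions and to compare classes of regions. Wider regions scored higher in both lists, with a Spearman rho across regions of 0.750 for CHD5 and 0.853 for H3K27me3. The lists hold no read counts, so depth and its effect on the number and width of regions are unknown.

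Coordinates were read from the lists and are given counted from 1. No rows of either list overlapped or touched each other. Overlap meant at least 1 shared bp. It was counted with a purpose-written routine and checked with bedtools 2.31.1, and both gave 712 overlapping CHD5 peaks. To ask how much overlap placement alone gives, all CHD5 peaks of a chromosome were moved by 1 random distance around that chromosome, which keeps their widths and spacing, in 1000 seeded draws. The span of a chromosome ran to the highest region end in either list. The number of shifts at least as far from the shifted mean as the observed value, in either direction, is given. By chromosome the same counts were adjusted by the Benjamini-Hochberg method over 23 chromosomes at a threshold of 0.05. Wilson 95% intervals cover counting error only. They treat each peak or domain as independent and can be too narrow, since CHD5 peaks lay in clusters.

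Scores of overlapping and other CHD5 peaks were compared by the difference of medians with 100000 two-sided permutations of the labels. H3K27me3 regions separated by up to 3 kb were joined into domains, and widths of domains with and without CHD5 were set against the same shifts. The analysis used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.

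The tests were run on simulated data first. In 40 simulations of shifted CHD5 peaks with no planted effect and 100 shifts each, the overlap test passed the threshold in 3 and the domain width test in 2. With overlapping peaks kept at a chance of 0.4, all 40 passed and the mean ratio was 0.422. The label permutation passed in 3 of 40 simulations with no effect and in 40 of 40 with scores multiplied by 0.8. Simulated positions came from the same kind of shift that the tests use, and labels were drawn independently for each peak. The simulations therefore check the routines, and not whether the shifts or permutations suit peaks that lie in clusters.

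Named positions follow a rule set before the data were examined: the 10 CHD5 peaks with the highest score, the 10 highest among those overlapping H3K27me3, and the 10 widest H3K27me3 domains. The 1-Mb windows and their correlation, the tests by chromosome, the distances beyond 1 kb, the classes of domain width, the domain sizes and H3K27me3 scores counted by region and the shifts of limited distance were chosen after the data were examined. The gene annotation at hand belongs to another build than the lists, and coordinates were not converted. Positions therefore carry no gene names, and distances to transcription starts, genes by promoter state and shares of gene lists were not analysed here. A sequence of the build was not used here either, so GC content was not examined.

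Alternatives covered the score limit in either list, the overlap that counts, the width of CHD5 peaks, the joining of H3K27me3 regions, the placement of random peaks and the chromosomes included.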

Results

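Chromatin immunoprecipitation followed by sequencing was carried out in SH-SY5Y, a human neuroblastoma cell line that takes on neuron-like features when treated with retinoic acid. The cells had been kept in 10 uM retinoic acid for 8 days. The series holds 4 libraries, each the only one of its group. A tagged form of CHD5, a chromodomain helicase that remodels nucleosomes, was pulled down on streptavidin beads. H3K27me3, the histone mark written by the Polycomb repressive complex, was precipitated with an antibody from the cells that carried the tagged protein. A pull-down from cells with the control construct and an input library complete the set. Lists of enriched regions were used for CHD5 and for H3K27me3, and no list was used here for the other 2 libraries. The lists carry no read counts, so the depth of each library is unknown. With 1 library per group there is no replicate error for any value, and intervals cover counting error only.

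CHD5 was found at 32543 peaks that covered 64.6 Mb of the genome, and H3K27me3 at 257073 regions that covered 87.1 Mb. On chromosomes 1 to 22 this came to 11.2 CHD5 peaks and 83.3 H3K27me3 regions per Mb. CHD5 peaks were densest on chromosome 17, with 19.9 per Mb, followed by chromosome 7 with 14.2 and chromosome 1 with 14.1. H3K27me3 regions were densest on chromosome 19, with 157 per Mb, followed by chromosome 6 with 132 and chromosome 7 with 126. Chromosome X held 276 CHD5 peaks, or 1.78 per Mb, against 16604 H3K27me3 regions, or 107 per Mb.

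The shape of the regions differed between the profiles. CHD5 peaks had a median width of 1647 bp, with the central 80% between 990 and 3361 bp. H3K27me3 regions had a median of 238 bp, with the central 80% between 150 and 595 bp. Many of the short H3K27me3 regions lay close together. Joining those separated by up to 3 kb gave 38537 domains with a median width of 1571 bp, of which 10180 were at least 5 kb wide. Those wider domains held 197041 of the regions, or 76.6%. The authors' score per region had a median of 117 for CHD5 peaks and 84.6 for H3K27me3 regions. Scores belong to their own list and were not compared between lists.

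Region widths varied between chromosomes in both lists. On chromosome 7 the median width was 2536 bp for CHD5 peaks and 351 bp for H3K27me3 regions. Chromosome 1 followed with 1950 and 295 bp, and chromosome 17 with 1910 and 262 bp. Chromosome X lay lower, with 1218.5 and 205 bp. Without replicates the spread of these medians between libraries is unknown.

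**Figure D1:**
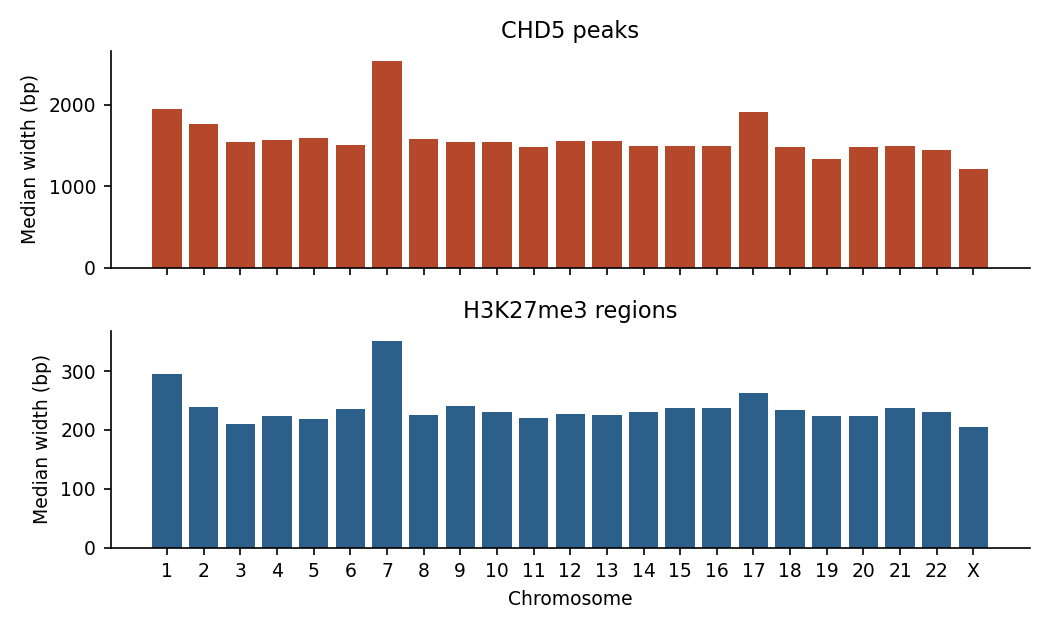
Median width in bp of CHD5 peaks (upper bars) and H3K27me3 regions (lower bars) on chromosomes 1 to 22 and X, 1 library each. In both lists chromosome 7 has the highest bar, at 2536 bp for CHD5 and 351 bp for H3K27me3.

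The first comparison set the positions of CHD5 against those of H3K27me3, since the study's title names both Polycomb repression and gene expression. CHD5 peaks and H3K27me3 regions mostly lay apart. Of the 32543 CHD5 peaks, 712 overlapped an H3K27me3 region by at least 1 bp, a share of 2.19% (Wilson 95% interval 2.03% to 2.35%). These peaks touched 1294 H3K27me3 regions, or 0.503% of that list. The overlapping peaks were mostly covered in part, with a median of 29.3% of the peak inside H3K27me3, and 374 of them met a region in a domain of at least 5 kb. The median CHD5 peak lay 166 kb from the nearest H3K27me3 region, with quartiles of 61.2 and 348 kb.

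Chromosome 16 held a window rich in both lists next to a window with H3K27me3 alone. The window from 85000001 to 86000000 had 66 CHD5 peaks, which was the second highest count of all 1-Mb windows. It also had 236 H3K27me3 regions, which no CHD5 peak overlapped, where the median autosomal window with a region of either list had 7. The adjoining window from 86000001 to 87000000 had 1023 H3K27me3 regions, the highest count, and 0 CHD5 peaks. The highest CHD5 count, 82 peaks, was on chromosome 10 from 80000001 to 81000000, where no H3K27me3 region was listed. On chromosome 17 from 55000001 to 56000000 there were 59 CHD5 peaks, and on chromosome 5 from 168000001 to 169000000 there were 56, again with no H3K27me3 region. Other windows rich in CHD5 did hold overlaps. Chromosome 1 from 156000001 to 157000000 also had 56 CHD5 peaks, of which 2 overlapped H3K27me3, and 7 H3K27me3 regions. On chromosome 17, 6 of 54 peaks from 48000001 to 49000000 overlapped H3K27me3, in a window with 33 regions, and 4 of 49 peaks from 71000001 to 72000000 did, in a window with 19. Conversely, chromosome 13 from 112000001 to 113000000 held 943 H3K27me3 regions and 2 CHD5 peaks, and chromosome 8 from 7000001 to 8000000 held 909 and 0. An exception among the windows richest in H3K27me3 was chromosome 18 from 76000001 to 77000000, with 794 regions, where 6 of 10 CHD5 peaks overlapped H3K27me3.

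**Figure D2:**
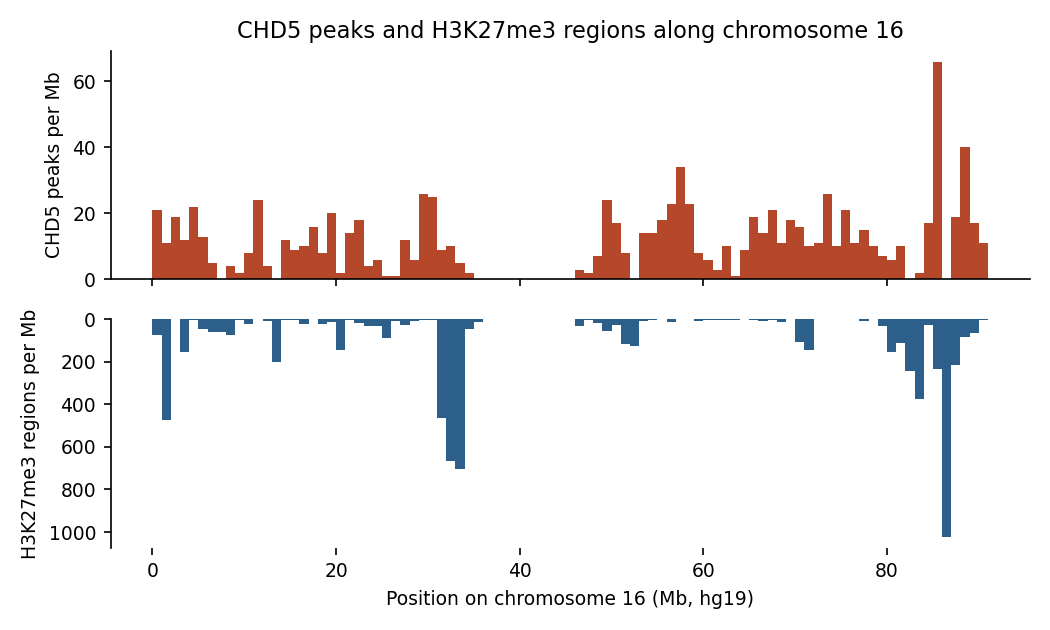
Number of CHD5 peaks (upper bars) and of H3K27me3 regions (lower bars, drawn downwards) in each 1-Mb window of chromosome 16, by position in Mb on hg19, 1 library each. The highest CHD5 bar, 66 peaks, stands next to the highest H3K27me3 bar, 1023 regions, whose window holds 0 CHD5 peaks. The window of the highest CHD5 bar also holds 236 H3K27me3 regions.

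The observed overlap was set against 1000 circular shifts of the CHD5 peaks within each chromosome. Shifted peaks overlapped H3K27me3 in 8.39% ± 0.349 of cases (SD over shifts, range 7.21% to 9.58%). The observed share was 0.261 times that mean, and 0 of 1000 shifts lay as far from the mean. This test concerns the placement of both profiles in these 2 libraries. It depends on how far the peaks are moved. In ranges of distance chosen after the data were examined, shifts of 10 to 50 kb gave 2.22%, a ratio of 0.986, with 148 of 200 shifts as far from their mean. Shifts of 3 to 10 kb gave 2.05%, a ratio of 1.06, with 10 of 200 as far. Shifts of 50 to 200 kb gave 3.27% and shifts of 1000 to 5000 kb gave 8.01%, with 0 of 200 as far in either range. The low overlap was therefore measured against positions more than 50 kb away, and not against the immediate surroundings of the peaks.

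**Figure D3:**
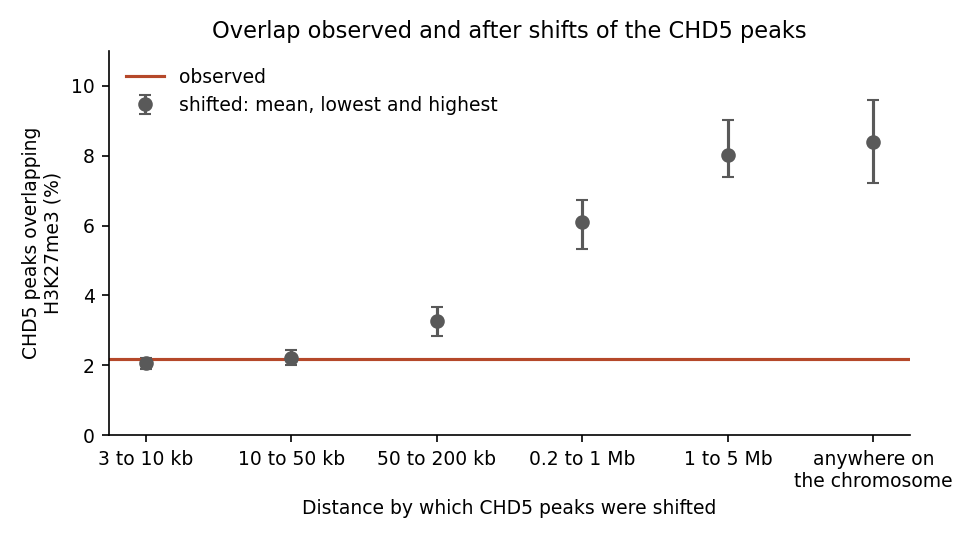
Percent of CHD5 peaks that overlap an H3K27me3 region, observed (line) and after shifting the CHD5 peaks (points, mean; bars, lowest and highest shift), by the distance of the shift. The line at 2.19% lies within the range of shifts of up to 50 kb and below every shift of more than 50 kb.

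Proximity, set only against shifts along the whole chromosome, followed the same direction, and its counts include the overlapping peaks. Within 10 kb of an H3K27me3 region lay 7.77% of CHD5 peaks, against 20.2% of shifted peaks, and within 100 kb lay 35.2% against 47.6%. In both cases 0 of 1000 shifts were as far from their mean. The 2731 autosomal windows of 1 Mb that held a region of either list were then compared. Their numbers of CHD5 peaks and of H3K27me3 regions had a Spearman rho of -0.411. Moving the CHD5 counts around each chromosome among these windows gave a range of -0.118 to 0.0669 over 1000 draws. Leaving out windows empty in both lists can lower the observed rho, and the moved counts were not filtered again. Windows are not independent replicates. Of the 275 windows with the most CHD5 peaks and the 274 with the most H3K27me3 regions, 3 were shared, where independent lists would share 27.6.

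By chromosome, the observed share lay below the shifted mean on all 23 chromosomes tested, Y being left out for its 17 CHD5 peaks. The difference passed the Benjamini-Hochberg adjusted threshold on 20 of them. Chromosome 8 had 17 overlapping peaks, or 1.15% against 11.3%. Chromosome 21 had the lowest ratio, 0.0936, from 3 overlapping peaks. Chromosomes 7 and 17, where regions of both lists were wider, had 106 and 79 overlapping peaks, at 4.70% against 14.6% and 4.88% against 10.98%. The difference did not pass on chromosomes 11, 22 and X. On X, 27 of 276 peaks overlapped, 9.78% against 11.2%, and 556 of 1000 shifts were as far. Whether the ratio differs between chromosomes was not tested.

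The next comparison asked whether CHD5 peaks that meet H3K27me3 differ in score from those that do not. They scored lower, while the H3K27me3 regions they touched scored higher than other H3K27me3 regions. The 712 overlapping peaks had a median score of 104 and the 31831 others a median of 117.5, a difference of -13.6, while their median widths were 1673.5 and 1647 bp. The overlapping share was 2.62% (Wilson 95% interval 2.29% to 2.99%) in the lowest quartile of scores, then 2.38% and 2.13%, and 1.62% (1.37% to 1.92%) in the highest. These intervals treat peaks as independent and can be too narrow for peaks in clusters. Peaks shifted along the whole chromosome went the opposite way, from 7.33% in the lowest quartile to 9.94% in the highest. The ratio of observed to shifted share went from 0.357 to 0.163. Shifts of limited distance were not split by quartile, so these ratios do not concern the immediate surroundings of the peaks. Peaks in the highest quartile were also wider, with a median of 2783 bp against 1103 bp in the lowest. In the H3K27me3 list, the 1294 regions touched by CHD5 had a median score of 113 against 84.5 for the others. The difference of 29.02 exceeded that of regions touched by peaks shifted along the whole chromosome, 8.20 ± 1.66 (SD over shifts), with 0 of 1000 shifts as far. Against shifts of limited distance the excess was smaller. Shifts of 3 to 10 kb gave 19.8 ± 2.95 and shifts of 10 to 50 kb gave 18.3 ± 3.29, with 0 of 200 as far in either range. The touched regions were also wider, with a median of 332.5 bp against 238 bp. Wider regions scored higher in this list, so the score difference is not separate from width.

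Among the peaks themselves, 10 shared the highest score of 3100. Of these, the peak on chromosome 7 from 1395499 to 1399295 overlapped H3K27me3, over 981 bp, in a domain of 124 kb. The peak on chromosome 16 from 89250504 to 89254831 lay 0.214 kb from a region. The others had their nearest H3K27me3 region between 73.5 and 431 kb away. They were on chromosome 10 from 488252 to 496491, chromosome 19 from 5230649 to 5235843, chromosome 21 from 45205445 to 45207944, chromosome 8 from 102634584 to 102637958, chromosome 9 from 137463059 to 137467288, and chromosome 2 from 1526212 to 1539169, from 29465388 to 29470592 and from 242947157 to 242954475.

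The highest scores among overlapping peaks after that on chromosome 7 were 1822 on chromosome 2 from 1218152 to 1227555, with 6067 bp inside H3K27me3, and 1422 on chromosome 12 from 132063082 to 132068538, with 455 bp. On chromosome 17, the peak from 8020562 to 8029820 scored 1342 and shared 1509 bp, and that from 1211117 to 1215370 scored 1169 and shared 4030 bp. The remaining 5 of the highest 10 scored between 859 and 1085. They lay on chromosome 1 from 217350813 to 217357555, chromosome 2 from 136869351 to 136872283, chromosome 16 from 1141719 to 1143797, and chromosome 4 from 189365860 to 189370789 and from 1420838 to 1423294. The difference of medians was tested by permuting the overlap labels of the peaks, and 346 of 100000 permutations were as far from 0. Neighbouring peaks are not independent, so this describes the list and is no replicate test.

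The last comparison asked whether H3K27me3 domains that hold CHD5 differ in width from those that do not. Few domains held CHD5. Counted by domain, those that did were wider, as wide domains are easier to hit, but less so than chance placement gave. A CHD5 peak lay in 664 of the 38537 domains, where shifted peaks reached 2234 ± 80.8 (SD over shifts), and 0 of 1000 shifts were as far from that mean. Domains with CHD5 had a median width of 4831.5 bp and those without 1530 bp. The difference of 3301.5 bp was below the 6784 ± 356 bp of the shifted peaks, with 0 of 1000 shifts as far. Counted by region, the 1294 H3K27me3 regions touched by CHD5 lay in smaller domains, with a median of 6.82 kb against 14.7 kb for the others. Regions touched by shifted peaks had a median of 16.8 ± 0.944 kb, with 0 of 1000 shifts as far.

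In each class of width the share of domains with CHD5 was below that of shifts along the whole chromosome. Of 17087 domains under 1 kb, 142 held CHD5, or 0.831% against 2.04%. Of 1696 domains from 20 to 50 kb, 68 did, or 4.01% (Wilson 95% interval 3.17% to 5.05%) against 23.7%. Of 422 domains of at least 50 kb, 53 did, or 12.6% (9.73% to 16.1%) against 43.1%. In all 5 classes 0 of 1000 shifts were as far from their mean. The limit on distance carried over to the number of domains. Shifts of 10 to 50 kb reached 656 domains, with 146 of 200 as far, and shifts of 3 to 10 kb reached 610.2, fewer than observed, with 0 of 200 as far. By width, against shifts of 10 to 50 kb, domains from 1 to 5 kb held CHD5 more often, at 1.71% against 1.14%, and those from 20 to 50 kb less often, at 4.01% against 7.14%. Those of at least 50 kb also held it less often, at 12.6% against 18.8%. In each of these 3 classes 0 of 200 shifts were as far, and the other classes, under 1 kb and from 5 to 20 kb, had 128 and 40 of 200 as far. Shifts of 3 to 10 kb gave the same directions, and there domains under 1 kb also held CHD5 more often, at 0.831% against 0.681%, with 3 of 200 as far. The width difference of 3301.5 bp stayed below that of shifts of 10 to 50 kb, 6317 ± 635 bp, with 0 of 200 as far.

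The widest domain lay on chromosome 7 from 149628944 to 149924212, spanned 295 kb and held 3 CHD5 peaks, with 17 more CHD5 peaks within 500 kb on either side. A domain of 236 kb on chromosome 17 from 46533318 to 46769108 held 2 CHD5 peaks, and 23 lay in its flanks. Nearby, the domain from 46238852 to 46450080 spanned 211 kb and held 0, with 30 in its flanks. The other 7 of the 10 widest, from 184 to 231 kb, also held 0. They lay on chromosome X from 52627157 to 52858314 and from 48093966 to 48291752, chromosome 14 from 19972847 to 20191999, chromosome 7 from 143869139 to 144082977, chromosome 8 from 7534112 to 7743881 and from 7282765 to 7474648, and chromosome 6 from 3364824 to 3548363. Flanks of the domain on chromosome 6 held 16 CHD5 peaks, and those of the domain on chromosome 14 held 0. The width result depends on joining the regions. With the regions left unjoined, those touched by CHD5 had a median of 332.5 bp against 238 bp, and the difference of 94.5 bp was above the 27.3 bp of the shifted peaks.

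**Figure D4:**
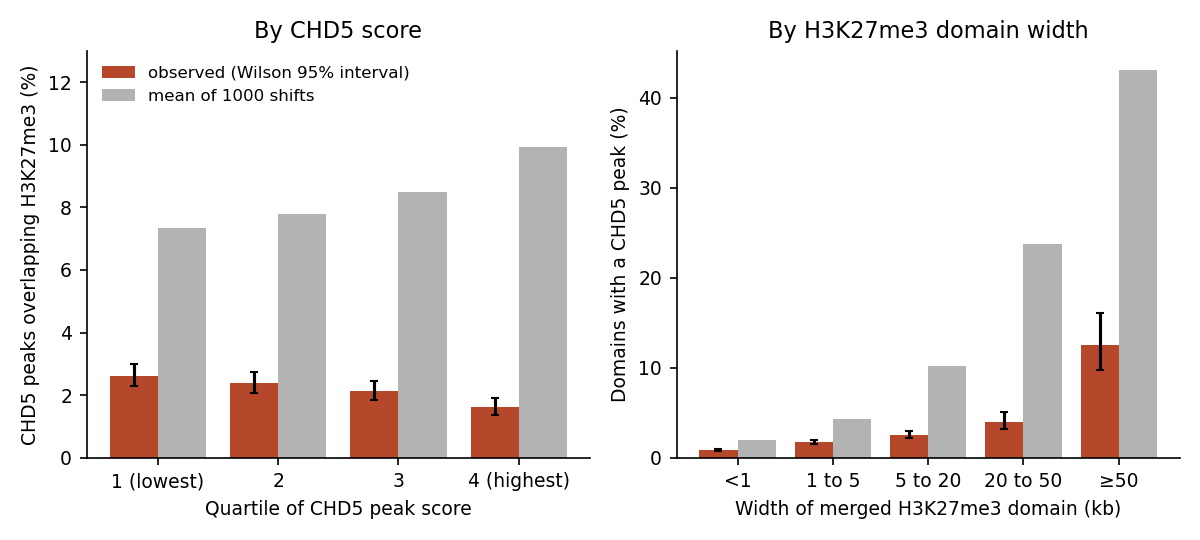
Left, percent of CHD5 peaks overlapping H3K27me3 by quartile of the CHD5 score; right, percent of H3K27me3 domains holding a CHD5 peak by domain width in kb. Coloured bars are observed values with Wilson 95% intervals (counting error only, 1 library each) and grey bars the mean of 1000 shifts; observed shares go from 2.62% to 1.62% with score and from 0.831% to 12.6% with width, each below its grey bar, which stands for shifts along the whole chromosome.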

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

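The shifts of limited distance, shifts within filled windows, peaks of middle width, regions in domains of at least 5 kb and the runs without chromosomes 1, 2, 7, 11, 17, X and Y were chosen after the data were examined. All other alternatives were set before.

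The low overlap kept its direction and its side of the threshold in 15 of 17 alternatives, with ratios of observed to shifted overlap from 0.187 to 0.670. The exceptions were shifts of 10 to 50 kb, with a ratio of 0.986, and shifts of 3 to 10 kb, with 1.06, where the direction turned and 10 of 200 shifts were as far. For both, the cause was not tested. The lower score of overlapping peaks held in 4 of 4 alternatives. The smaller width difference of domains with CHD5, relative to shifted peaks, held in 10 of 11, shifts of limited distance included, although the number of domains with CHD5 was no longer low against shifts of up to 50 kb. With regions left unjoined it turned, at 94.5 bp against 27.3 bp for shifted peaks, and the cause was not tested. Counts moved with the limits: scores at or above the median left 16272 CHD5 peaks and 128626 H3K27me3 regions, and joining across 3 kb gave 38537 H3K27me3 domains.

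Not run for want of an annotation or sequence of the build were all alternatives on transcription starts, promoter state, gene lists, promoter peaks and GC content. Depth is unknown for both lists, so neither a missing region nor the difference in number between lists can be read as a difference in occupancy.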

Other observations

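All tests in this part were chosen after the result was seen, except that of isolated CHD5 peaks on chromosome 7.

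CHD5 peaks lay in clusters. Another CHD5 peak was within 10 kb of 15650 peaks, or 48.1%, against 24.1% ± 0.332 (SD) in 100 uniform draws within chromosomes.

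CHD5 peaks seldom overlapped H3K27me3 regions. Assembly gaps are argued against, since shifts kept within filled 1-Mb windows left a ratio of 0.249, and so are segments with other region widths, since the chromosomes without them gave 0.187. That the profiles may occupy separate large domains is a hypothesis that stays open. Shifts of 10 to 50 kb gave a ratio of 0.986, against 0.670 for 50 to 200 kb and 0.273 for 1000 to 5000 kb. Over all peaks, the overlap was thus low only against positions more than 50 kb away. The classes of domain width departed in both directions from the shifts of 10 to 50 kb. The share of domains with CHD5 was 1.497 times that of these shifts for domains of 1 to 5 kb. It was 0.562 times for 20 to 50 kb and 0.669 times for at least 50 kb. The ratio over all peaks averages these departures, so it cannot show whether separate large domains account for the low overlap. Background of the pull-down that follows accessible chromatin could give the same picture and cannot be told apart from binding, because the control pull-down is among the 2 libraries with no region list used here.

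Both lists held wider regions in the same segments, and narrower ones on the end of chromosome 11. The segments were bounded where the CHD5 widths change, which in part sets the CHD5 contrasts, and the H3K27me3 widths changed 0.325 and 0.846 Mb away on chromosomes 1 and 17 but 11.8 and 14.2 Mb away on chromosomes 2 and 11. Against medians of 1526 bp for CHD5 and 229 bp for H3K27me3 on the other autosomes, the medians were 2473 and 341 bp on chromosome 1 beyond 120 Mb, 2419.5 and 308 bp on chromosome 2 before 48.7 Mb, 2334 and 343 bp on chromosome 17 beyond 45.0 Mb, and 1136 and 166.5 bp on chromosome 11 beyond 80.5 Mb, where CHD5 peaks also thinned from 13.8 to 1.69 per Mb and H3K27me3 regions from 66.2 to 11.8 per Mb. Broader CHD5 binding alone is argued against by H3K27me3 regions on chromosome 7, which were 1.53 times as wide as on the other autosomes. Joining of dense CHD5 peaks would not widen H3K27me3 regions either, so the same value argues against it as the only cause in both lists. Whether joining widened the CHD5 peaks stays open. CHD5 peaks there with no other within 20 kb were 1.68 times as wide, the outcome set beforehand as speaking against joining. A joined cluster would itself count as such a peak, however. Copy number or depth of the segments, gains and losses being common in neuroblastoma, could widen regions in both lists. That explanation stays open, because copy number was not measured here. Widths correlated with a Spearman rho of 0.376 over 154 windows of 20 Mb. Change points fell within 5 Mb of each other on 2 of 4 chromosomes, and this count cannot decide the question. The same search on chromosomes 3, 4, 5, 6, 8, 9, 10 and 12 placed them 14.3 to 149 Mb apart, and on chromosome 7 10.9 Mb apart. On chromosomes 3 to 6, 8 to 10 and 12 the CHD5 widths changed only by factors of 0.893 to 1.15. The factors were 1.64 on chromosome 1 and 1.55 on chromosome 17, so change points without a marked step are a weak reference. H3K27me3 regions were sparse between the change points of both lists on chromosome 2, and less so on chromosome 11. The H3K27me3 change point was therefore poorly placed on chromosome 2, and its distance there speaks neither for nor against a shared boundary.

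Chromosome Y held 17 CHD5 peaks, of which 13 lay in its first 3 Mb. Of these 13, 61.5% overlapped a CHD5 peak of chromosome X once moved by 50 kb, or 8 peaks, where the highest of 390 other offsets matched 3. The H3K27me3 list held 675 regions on Y, of which 131 lay in its first 3 Mb. Of these 131, 85 matched at that offset and at most 15 at the others. Regions of Y beyond its first 3 Mb were not examined in either list. Reads shared by the tips of X and Y are a candidate source of the CHD5 peaks in the first 3 Mb, and no biological explanation was tested.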
